A study of Mus musculus with 12 samples.

How the data were processed

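Sorted CD4-CD8 double-negative thymocytes of wild-type (6 arrays), NHD13 (3 arrays) and NHD13 Lyl1-knockout mice (3 arrays) were measured on 12 Illumina MouseWG-6 v2.0 beadchip arrays, with RNA from RNeasy columns, per the labels. BeadStudio and limma are named as processing tools, without role or version, per the labels. The bead-summarised signal of each of 45281 probes is an intensity in 1 colour, per the file headers; whether background was subtracted in BeadStudio is not given in the sources used here, but no value lies near 0. Beside each signal stands a detection p-value, per the file headers, which compares the probe with the array's negative controls. The authors also deposited a table of log2 levels, and its columns share nearly the same quartiles (medians of 4.86 on each array, minimum 4.30); the step that made them is not given in the sources used here. That table's values correlate at 0.9998 with the normalization made here and differ from it by a mean of 0.110 to 0.112, and it served as an alternative.

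The intensities were normalized with neqc of limma 3.58.1 in R 4.3.3: the background was modelled from the signals that the detection p-values give to the negative controls, an offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale. Probes with a detection p-value under 0.05 on at least 3 arrays were kept (20416). The probe annotation gave 34885 probes 1 gene symbol, 18 several and 10378 none; 0 symbols had to be updated, and 16916 kept probes had 1 symbol. A gene took the values of its kept probe with the highest mean signal, which gave 10497 genes, and its other probes were checked for disagreement: of the named genes with more probes, 16 of 37, 17 of 38 and 19 of 38 had a probe that differed in call or direction in the 3 comparisons, in the order of the report, with 1, 0 and 0 called in opposite directions. The order of genes along chromosomes, used for neighbours only, was that of assembly GRCm38.p6.

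All 12 arrays were fitted together with a mean per group (lmFit), and NHD13 against wild type, the knockout group against NHD13 and the knockout group against wild type were tested as contrasts with limma's moderated test (eBayes), adjusted by Benjamini and Hochberg over the kept probes, with calls at an adjusted p under 0.05. Changes are log2 differences with their standard errors (SE). Levels are group means with their SD. A fold against a group in which no array detected the probe is a lower bound, set against the signal at which detection starts, and is printed as "at least". After values were seen, the same bound was also used for the genes named in the text where the dimmer group's mean lies under that signal although some of its arrays detect the probe. The counts of genes called in opposite directions in the first 2 comparisons were also set against simulated and reassigned groups after they were seen. The number of arrays limits the precision: planted changes of 2-fold, 4-fold and 8-fold in data simulated from these arrays (20416 probes) were recovered for 38.8%, 88.1% and 93.9% of the changed probes in the 1st comparison, 17.9%, 80.6% and 97.0% in the 2nd and 50.7%, 92.5% and 98.5% in the 3rd, with 5 of 152, 8 of 138 and 7 of 168 calls false. The 1st and 3rd simulations differ only in the random draw, so the gap between them is no difference in precision. The simulated groups had equal spread and no background class, sex or outlying array. False calls from those sources were not tested.

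The lists number 23, with 316 genes, 290 of them with a probe named for them and 224 measured: stem and progenitor genes, early thymocyte regulators, HOX genes and cofactors, DN3 genes, Notch targets, genes of CD4+CD8+ and later thymocytes, T-lineage transcription factors, T cell receptor signalling, the cell cycle, ribosome biogenesis and MYC targets, p53 targets, the BCL2 family, interferon response, immediate early and heat shock genes, sex-linked genes, and markers of gamma delta T cells, NK and innate lymphoid cells, B cells, myeloid cells, dendritic cells, erythroid cells, megakaryocytes and mast cells, and thymic stroma. Each list was tested with camera, which compares its genes with all others, with a preset correlation between genes of 0.01, adjusted over the 23 lists of a comparison. A list with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, were alternatives. A list planted as shifted in simulated data (10497 genes) was called in all 3 comparisons, 1 other list was called in the 1st, and 0 lists were called without a shift. The simulated genes were drawn independently, so false calls that correlated genes can give with the preset 0.01 were not tested. The counts "adjusted over the list alone" repeat the Benjamini and Hochberg step within the list.

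The comparisons, tests, filters, gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. Under that rule the text names Lyl1, Lmo2, Hoxd13 and Nup98 always. Per comparison it names the 12 genes that rose most and the 12 that fell most among those called, provided that the groups do not overlap, the probe has 1 proper gene symbol and every array of the higher group detects it. From each list it takes up to 4 members with the smallest adjusted p. Mpo, Cd3e, Tal1, Meis1 for NHD13 against wild type, Mcm7, the 2nd and later values of Cd8b1, and the genes of the last part that the report does not name were singled out after their values were seen.

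Shared changes of both transgenic groups were measured as the covariance and correlation across 10497 genes of their changes against wild type, with the 6 wild-type arrays divided between the comparisons in all 20 ways, and as the count of genes called in both. Groups without change were simulated against the same wild-type arrays (100 times for the covariance, 20 times for the count). The position of an array is its projection on the line from the wild-type mean to the NHD13 mean over the genes called between these groups, with the array left out of its own group's mean.

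The alternatives were median scaling without the quantile step, the authors' deposited table, an offset of 50, no filter on dim probes, a detection p-value under 0.01, eBayes with trend and robust, fits of only the groups compared, array weights, the mean of a gene's probes, a minimum change of 2-fold, the replicate number as a block, and leaving out each array in turn. Alternatives added after the data were seen were the background class as a block, the sex of the mice as a covariate, and comparisons with only wild-type replicates 1 to 3 or 4 to 6. Against wild type some of these coincide. The class block sets NHD13 against wild-type replicates 4 to 6 and the knockout group against replicates 1 to 3. The replicate block sets both groups against replicates 1 to 3. Such blocks share their log2 changes with the restricted comparisons and differ in the estimated spread only. Background classes came from average-linkage clustering of the correlations between arrays over 19512 undetected probes, and sex from Xist and Y-linked genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes without a gene symbol enter the counts of probes and nothing else, and Hoxd13 was not tested, since its probe was not kept.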

Results

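RNA from sorted CD4-CD8 double-negative (DN) thymocytes, the earliest T-cell precursors in the thymus, was measured on 12 mouse arrays (Illumina MouseWG-6 v2.0 beadchips), each with 45281 probes. The 3 groups were wild type (6 arrays), NHD13 (3 arrays) and NHD13 Lyl1-knockout (3 arrays, called the knockout group from here on). NHD13 mice carry a transgene that makes a fusion of the nucleoporin Nup98 with the homeobox protein Hoxd13, a fusion known from human leukaemia. The knockout group carries the same transgene and lacks Lyl1, a basic helix-loop-helix transcription factor of blood progenitors. The labels give C57 BL/6 mice aged 2 to 3 months and 300 ng of RNA per array. The series asks whether the fusion gives thymocytes the power of self-renewal through Lmo2, a LIM-domain adaptor protein, and Lyl1. No group lacks Lyl1 without carrying the transgene. The effect of losing Lyl1 on its own, and an interaction of the 2 changes, could therefore not be tested. Nothing in the labels says that the arrays of a group came from separate animals, and all errors and p-values measure only the spread between these samples.

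Each array detected between 17168 and 19464 probes (37.9% to 43.0%), and the summed signal per array ran from 18826400 to 35384700 intensity units. After the filter on dim probes 20416 probes were compared, and 10497 genes had at least 1 of them. The number of arrays limits the precision. Correlations between arrays of a group ran from 0.944 to 0.991 in wild type, 0.955 to 0.963 in NHD13 and 0.897 to 0.969 in the knockout group. In the knockout group, replicate 1 stood apart. Its log2 signal of Mpo, an enzyme of neutrophil granules, was 14.3 against 5.27 and 4.64 in replicates 2 and 3. That of Cd3e, a chain of the T cell receptor complex, was 9.58 against 13.1 in both others. The signal of undetected probes put the arrays into 2 background classes. The first held wild-type replicates 1 to 3 and the whole knockout group, the other wild-type replicates 4 to 6 and all NHD13 arrays. By Xist and Y-linked genes, wild-type replicates 1 to 3 and knockout replicate 3 were male. Wild-type replicates 4 to 6, all NHD13 arrays and knockout replicates 1 and 2 were female.

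The Lyl1 probe (ILMN_2612255) separated the 3 groups on every array. Its log2 signal in wild-type replicates 1 to 6 was 7.34, 7.05, 7.21, 7.37, 7.39 and 6.79. In NHD13 replicates 1 to 3 it was 11.18, 11.19 and 11.10, and in knockout replicates 1 to 3 it was 4.75, 4.73 and 4.68. No knockout array detected it, as shares of 0.406, 0.457 and 0.514 of the negative controls were at least as bright. The probe for Hoxd13, a part of the fusion, was detected on 1 of the 12 arrays and was not tested. Nup98, its other part, fell by 0.55 log2 in NHD13 against wild type by its brightest probe (adjusted p = 0.0457), while its other 2 probes were at −0.29 and 0.48 and not called. That call ended without NHD13 replicate 2 (adjusted p = 0.215) or 1 (adjusted p = 0.0875) and without any wild-type array except replicate 5 (adjusted p between 0.0527 and 0.0806). No probe sequences were at hand, so whether the Hoxd13 and Nup98 probes read the fusion transcript was not checked. Their values cannot be taken as the level of the fusion.

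**Figure D1:**
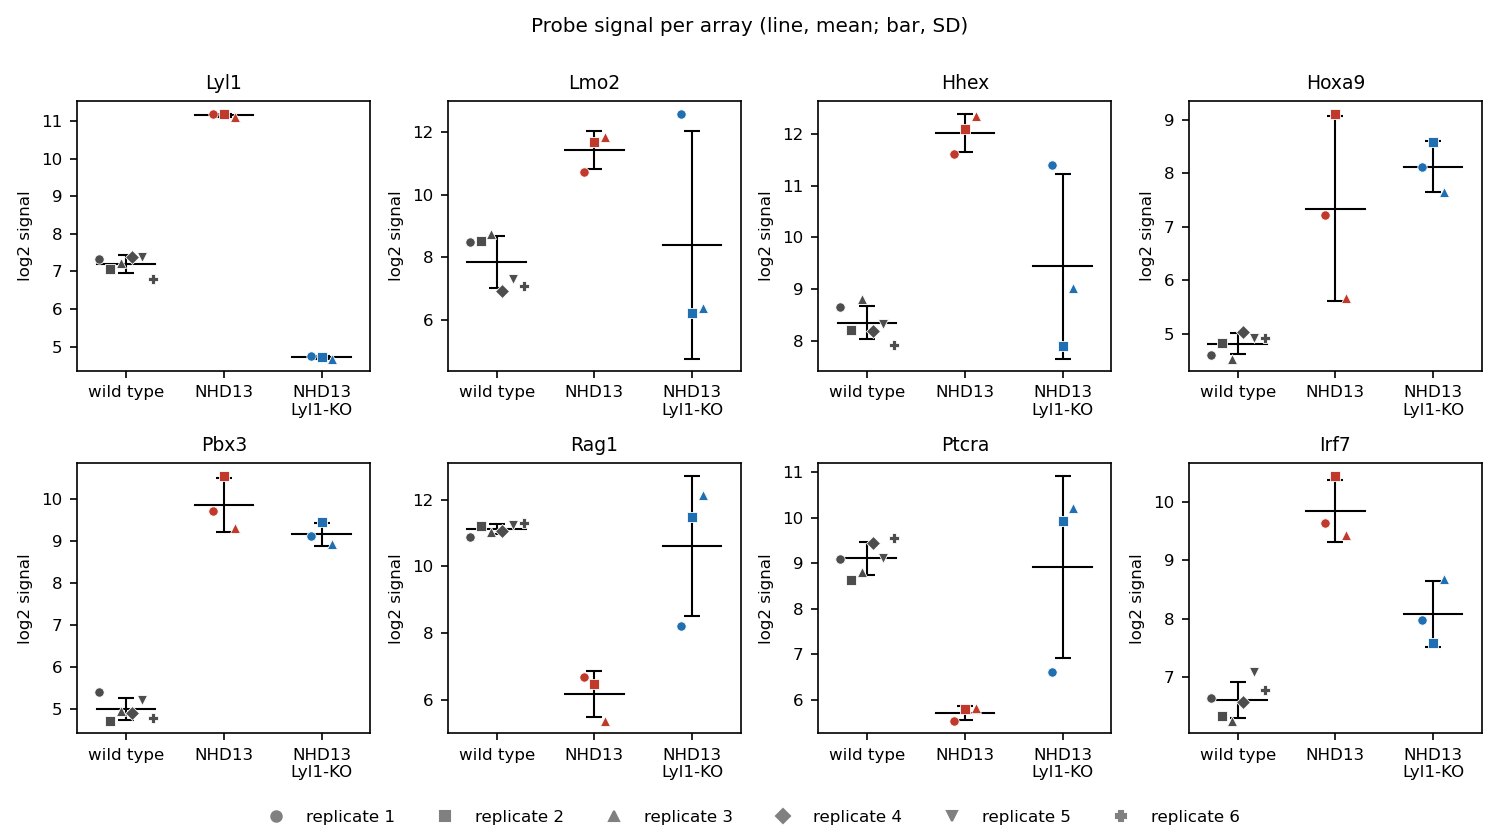
Log2 signal of 8 genes (vertical axis) on each of the 12 arrays, by group; each point is an array with a marker for its replicate number, the line is the group mean and the bar its SD. Lyl1 lies near 7.19 in wild type, 11.15 in NHD13 and 4.72 in the knockout group, and Lmo2 is 12.6 in knockout replicate 1 but 6.21 and 6.37 in replicates 2 and 3.

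The comparison of NHD13 with wild type asks what the fusion changes in DN thymocytes. Each array reads sorted cells in bulk. In all 3 comparisons, a change within cells therefore cannot be told from a shift in cell stages or types. Several regulators of blood stem cells and progenitors rose, 9 of the 16 measured on their list, though the list's call was lost with an estimated correlation (adjusted p = 0.335). Lyl1 was 15.6-fold higher (log2 change 3.96 ± 0.16 SE, adjusted p = 1.08e-07), at 11.15 ± 0.05 in 3 arrays against 7.19 ± 0.23 in 6 (mean ± SD). Lmo2 was 12.1-fold higher (3.60 ± 1.14, adjusted p = 0.0415) and the homeobox gene Hhex 12.6-fold (3.66 ± 0.56, adjusted p = 0.00119). Of the HOX genes and cofactors 10 of 19 rose, among them Pbx3 by at least 22.1-fold (adjusted p = 5.87e-07), though the list's call was lost with an estimated correlation (adjusted p = 0.155). Rag1 and Ptcra, both on the DN3 list, fell, while that list was not called (adjusted p = 0.120). Rag1, which makes the recombinase that joins receptor gene segments, was 30.8-fold lower (6.18 ± 0.70 against 11.12 ± 0.16, adjusted p = 5.46e-04). Ptcra, the alpha chain of the receptor's first form, was 10.5-fold lower (adjusted p = 0.00306). Of the cell cycle genes 19 of 20 fell and of the interferon response genes 8 of 9 rose, though both list calls were lost with an estimated correlation (adjusted p = 0.335 and 0.234). The call for Lmo2 ended on leaving out any single NHD13 or wild-type array. Its change was then between 3.38 (adjusted p = 0.139, without NHD13 replicate 3) and 3.94 (adjusted p = 0.0638, without NHD13 replicate 1). All 12 arrays were fitted together, so the SE of Lmo2 also holds the spread within the knockout group. There replicate 1 lay far above replicates 2 and 3. Without that array, the knockout group's change against NHD13 went from −3.04 (adjusted p = 0.121) to −5.14 (adjusted p = 2.38e-04). No knockout array was left out for NHD13 against wild type. The lost calls therefore cannot tell spread within NHD13 or wild type from spread within the knockout group.

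Among the lists fixed beforehand, HOX genes and cofactors had 10 of 19 measured members higher and 0 lower (13 and 0 adjusted over the list alone). The median log2 change was 1.67 and the mean 1.89 (camera set test up, adjusted p = 7.03e-07, and adjusted p = 0.155 with an estimated correlation). Where no count adjusted over the list alone stands beside a list, it was the same as the first. Hoxc6 was at least 37.0-fold higher, as no wild-type array detected it, and Hoxa5 (4.15), Hoxa7 (3.49) and Hoxa2 (at least 6.55-fold) rose with it. For the cofactor Meis1, detected on 2 of 6 wild-type and 0 of 3 NHD13 arrays, both group means lay in the background and no change can be read. Stem and progenitor genes had 9 of 16 higher and 0 lower. Their median was 1.86 and their mean 1.82 (adjusted p = 1.78e-04, and adjusted p = 0.335 with an estimated correlation). Besides Lyl1, Lmo2 and Hhex these included Kit, the receptor for stem cell factor (2.76 ± 0.39, adjusted p = 7.65e-04), and Gfi1b, a repressor of blood progenitors (at least 6.39-fold). Tal1, a close relative of Lyl1, was likewise in the background in both groups (detected on 1 of 6 and 1 of 3 arrays). The early thymocyte list shares 12 genes with this one and had 7 of 14 higher and 0 lower (7 and 1 adjusted over the list alone). Its median was 2.00 and its mean 1.40 (adjusted p = 0.00805, and adjusted p = 0.605 with an estimated correlation). That call ended with median scaling (adjusted p = 0.111), with the replicate number as a block (adjusted p = 0.0914) and against wild-type replicates 1 to 3 alone (adjusted p = 0.0722). The replicate block and that restriction are the same comparison in effect.

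The lists of DN3 genes, Notch targets, later thymocytes, T-lineage factors and receptor signalling were not called. Of 16 measured DN3 genes, markers of the stage at which the first receptor chain is tested, 1 rose and 6 fell. Their median was −0.56 and their mean −0.86 (set test down, adjusted p = 0.120, and 0.0103 with median scaling). Ets2 fell (−1.81, adjusted p = 0.00276) with Rag1 and Ptcra, while Dtx1, a Notch target, rose (1.86, adjusted p = 0.00557). The Notch list shares 6 genes with it and had 2 of 11 higher and 3 lower (3 and 3 adjusted over the list alone). Its median was 0.20 and its mean −0.15 (set test up, adjusted p = 0.914). Myc, a growth regulator and Notch target, fell by 2.15 (adjusted p = 7.59e-04). Of 11 genes of CD4+CD8+ and later thymocytes 4 rose and 2 fell, with a median of −0.11 and a mean of 0.37 (set test up, adjusted p = 0.445). Klf2, a factor of cells ready to leave the thymus (2.70, adjusted p = 0.00183), and the homing receptor Ccr7 (1.82, adjusted p = 4.53e-04) were among those that rose. For Cd8b1 the probes disagreed: the brightest rose by 1.09 (adjusted p = 0.0158, and 0.0914 without NHD13 replicate 2) and the others fell, at −4.94 and −5.83. Of 10 T-lineage transcription factors 1 rose, Myb (1.31, adjusted p = 0.00881, and 0.0535 without NHD13 replicate 2), with its other 2 probes at 0.50 and 0.88. Lef1 fell (−3.03, adjusted p = 0.0264), which ended without NHD13 replicate 2 (adjusted p = 0.0714) or 3 (adjusted p = 0.116). The list's median was −0.09 and its mean −0.24 (set test down, adjusted p = 0.914). T cell receptor signalling genes had 0 of 12 higher and 2 lower (median −0.07, mean −0.44, adjusted p = 0.676).

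Cell cycle genes had 19 of 20 measured members lower and 0 higher (20 and 0 adjusted over the list alone). Their median was −1.32 and their mean −1.28 (adjusted p = 9.51e-09, and adjusted p = 0.335 with an estimated correlation). Tyms, which makes thymidylate, fell by 1.72 (adjusted p = 0.00278). The replication clamp Pcna fell by 1.32 and the replication licensing factor Cdc6 fell by 1.68, with its other probe at −0.83. Mcm7 alone missed the threshold (−0.81, adjusted p = 0.0545). Ribosome biogenesis genes and MYC targets had 10 of 13 lower and 0 higher. Their median was −0.89 and their mean −0.84 (adjusted p = 2.63e-06, and adjusted p = 0.234 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, fell by 1.33 ± 0.16 (adjusted p = 2.48e-04), and the nucleolar protein gene Ncl was 1.99-fold lower (adjusted p = 0.00268). Interferon response genes had 8 of 9 higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 2.75 and their mean 2.41 (adjusted p = 8.41e-08, and adjusted p = 0.234 with an estimated correlation). The interferon regulatory factor Irf7 rose by 3.24 ± 0.29 (adjusted p = 4.55e-05), Isg15 by 3.22, Usp18 by 2.88 and Rtp4 by at least 6.11-fold. The per-array mean of the cell cycle list was −0.45, −1.49 and −1.91 against the wild-type mean in NHD13 replicates 1, 2 and 3. That of the interferon list was 2.36, 2.87 and 2.00. Of 13 p53 targets 2 rose and 1 fell (2 and 2 adjusted over the list alone), with a median of 0.26 and a mean of 0.15 (adjusted p = 0.445). Bbc3, a trigger of cell death, was at 1.53 (adjusted p = 3.01e-04). The BCL2 family had 1 of 9 higher and 0 lower (median −0.05, mean 0.10, set test up, adjusted p = 0.750). Immediate early and heat shock genes had 1 of 10 higher and 0 lower (median −0.12, mean −0.17, set test up, adjusted p = 0.928).

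Among markers of other cell types, those of gamma delta T cells had 3 of 7 higher (median 1.23, mean 0.89, adjusted p = 0.120, and 0.0459 without NHD13 replicate 3). Sox13, a regulator of that lineage, rose by 1.23 (adjusted p = 0.0249). NK and innate lymphoid markers had 1 of 10 higher and 3 lower (median −0.45, mean −0.61, adjusted p = 0.445), and Nkg7 rose by 1.47 (adjusted p = 0.00668). Of 3 erythroid markers 2 rose (median 2.38, mean 2.67, adjusted p = 0.0480). That list's adjusted p was 0.298 with an estimated correlation. It was 0.101 without NHD13 replicate 1, 0.0771 without replicate 2 and between 0.0554 and 0.0584 without wild-type replicate 1, 3, 5 or 6. With the authors' table it was 0.0502, and it lay between there and 0.115 with median scaling, either block, the sex covariate or either wild-type set. The globin gene Hba-a1 rose (5.24 ± 0.78, adjusted p = 0.00104), though its probe may also read its close copies. Of 15 myeloid markers none passed (median 0.12, mean 0.22, adjusted p = 0.992), with array means of −0.28, 1.85 and −0.90 in NHD13 replicates 1 to 3. B cell markers had 0 of 6 called (median −0.17, mean −0.14, adjusted p = 0.914) and dendritic cell markers 1 of 10 higher (median −0.99, mean −0.61, adjusted p = 0.445). Megakaryocyte and mast cell markers had 1 of 4 higher (median 0.42, mean 0.84, adjusted p = 0.445) and thymic stroma markers 2 of 7 (median 0.26, mean 0.40, adjusted p = 0.144). Sex-linked genes had 0 of 4 called (median −0.97, mean −0.39, adjusted p = 0.852).

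Here and in the later comparisons genes are listed by fitted log2 change, so places among genes with only a lower bound are not firm. By the naming rule, the largest fitted rise was in Olfm5, a secreted olfactomedin (at least 74.4-fold, adjusted p = 4.54e-06). Next came Hoxc6, the ubiquilin-like gene Ubqlnl (at least 29.4-fold, adjusted p = 1.08e-07), Stfa1, Mrvi1 (at least 28.8-fold, adjusted p = 1.24e-07), Hba-a1 and Lcn4 (5.08). The lectin receptor Clec4e (4.92), Pbx3, Zfpm2 (at least 17.2-fold), Fam20a (at least 17.2-fold) and Stx3, a membrane fusion protein (at least 18.4-fold), followed. Stfa1, 1 of several near-identical genes, was at least 27.4-fold higher (adjusted p = 0.0452) with an SD of 3.68 in NHD13. Its adjusted p was 0.227 without NHD13 replicate 2, 0.0947 without replicate 1 and between 0.0648 and 0.0711 without any wild-type array. The largest falls were in Dgkeos (at least 21.7-fold), Rag1, Trbv13-1, Klra3 (−4.87), Klra10 (−4.51), Akr1c12 (−4.10) and the glucose transporter gene Slc5a9 (at least 13.5-fold). Vopp1 (at least 10.1-fold, adjusted p = 4.15e-07), Bahcc1 (at least 12.6-fold), the semaphorin receptor Nrp1 (−3.82 ± 0.26, adjusted p = 4.37e-06), Rps6kl1 (at least 8.57-fold) and the DNA repair enzyme Mgmt (at least 8.45-fold) followed. Trbv13-1, Klra3 and Klra10 belong to families of similar genes, so which member their probes read is uncertain. The other probe of Zfpm2 was at −0.23, so its rise rests on 1 of 2 probes that disagree. The other 2 probes of Bahcc1 changed less (−0.74 and −0.58). The call for Trbv13-1 (−4.88, adjusted p = 0.014) ended without NHD13 replicate 3 (−4.16, adjusted p = 0.0788).

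By limma's moderated test, 4295 of 20416 probes passed an adjusted p of 0.05, 1999 higher and 2296 lower in NHD13, which makes 2541 of 10497 genes (1216 higher, 1325 lower). Median scaling in place of quantile normalization called 4294 probes, 3456 of them higher, with the median of all genes at 0.284 in place of −0.0011. Against wild-type replicates 4 to 6 alone, which share the background class and the sex of the NHD13 arrays, 2780 probes passed. Against replicates 1 to 3 alone, of the other class and sex, it was 4475 (2270 higher, 2205 lower). Without NHD13 replicate 3 it was 2246 probes and without replicate 2 it was 2361.

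**Figure D2:**
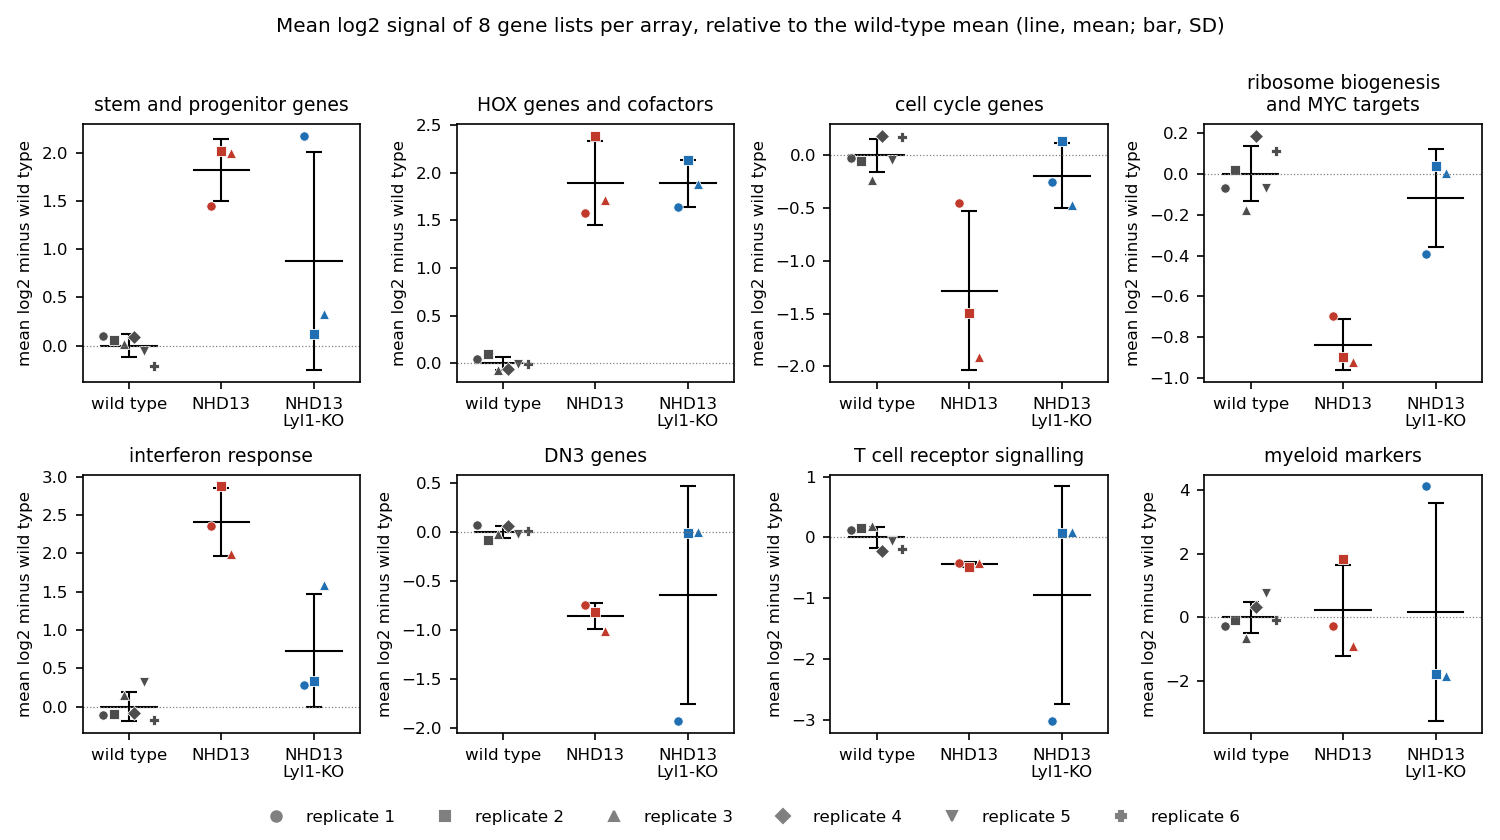
Mean log2 signal of the measured members of 8 gene lists minus the wild-type mean (vertical axis) on each of the 12 arrays, by group; points are arrays with a marker for their replicate number, the line is the group mean and the bar its SD. The HOX list lies between 1.57 and 2.39 on every transgenic array, while the myeloid list is at 4.13 in knockout replicate 1 and at −1.78 and −1.86 in replicates 2 and 3.

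The comparison of the knockout group with NHD13 asks what the loss of Lyl1 changes in thymocytes that carry the fusion. Rag1 rose 21.6-fold (4.44 ± 0.75, adjusted p = 0.0025) and Ptcra 9.20-fold (3.20 ± 0.71, adjusted p = 0.00906), with 3 arrays in each group. Of the cell cycle genes 8 of 20 rose and of the interferon response genes 7 of 9 fell, though both list calls were lost with an estimated correlation (adjusted p = 0.80 for each). Of 19 measured HOX genes and cofactors 1 was called, Hoxa3, which fell (−1.12, adjusted p = 0.0342, and 0.132 without NHD13 replicate 2). Lmo2 was not called (−3.04 ± 1.31, adjusted p = 0.121). Its log2 signal was 12.6 in knockout replicate 1 and 6.21 and 6.37 in the others, against 10.7, 11.7 and 11.9 in NHD13. Without knockout replicate 1 it fell by 5.14 (adjusted p = 2.38e-04). Nup98 rose by 0.67 (adjusted p = 0.0378), while its other 2 probes were at −0.51 and 0.44 and not called. That call ended without any single array except NHD13 replicate 3 (adjusted p between 0.0621 and 0.148).

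Stem and progenitor genes had 0 of 16 higher and 4 lower (1 and 4 adjusted over the list alone), with a median of −0.35 and a mean of −0.95 (set test down, adjusted p = 0.118). Early thymocyte regulators had 0 of 14 higher and 4 lower (1 and 4 adjusted over the list alone), with a median of −0.46 and a mean of −0.74 (adjusted p = 0.218). Without knockout replicate 1 both lists passed, each with an adjusted p of 4.35e-04. Besides Lyl1, the members that fell were Hhex (−2.57, adjusted p = 0.0155), Nfe2, a factor of red cell and platelet precursors (−3.71, adjusted p = 0.017), and Kit (−1.40, adjusted p = 0.0424). Each call ended without some single arrays. The adjusted p was 0.0527 and 0.0565 for Hhex without NHD13 replicates 2 and 3. For Nfe2 it was 0.0589, 0.0643 and 0.0541 without NHD13 replicate 2 and knockout replicates 2 and 3. For Kit it was 0.161, 0.0818, 0.140 and 0.0586 without NHD13 replicates 2 and 3 and knockout replicates 2 and 3. Hhex had a log2 signal of 11.4, 7.91 and 9.02 and Kit of 12.49, 10.58 and 11.97 in knockout replicates 1 to 3. The HOX list had 0 higher and 1 lower of 19 (0 and 0 adjusted over the list alone), with a median of −0.15 and a mean of −0.0036 (adjusted p = 0.556). The call for Hoxa3 ended without knockout replicate 1 (adjusted p = 0.0911) or 3 (adjusted p = 0.103) and without NHD13 replicate 2 (adjusted p = 0.132) or 3 (adjusted p = 0.125).

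Cell cycle genes had 8 of 20 higher and 0 lower (17 and 0 adjusted over the list alone). Their median was 1.02 and their mean 1.09 (adjusted p = 2.66e-05, and adjusted p = 0.80 with an estimated correlation). The mitotic kinases Aurkb (2.04, adjusted p = 0.0137) and Aurka (1.75, adjusted p = 0.0131) rose. The call for Aurka ended without NHD13 replicate 2 (adjusted p = 0.0539) or 3 (adjusted p = 0.0527) or knockout replicate 2 (adjusted p = 0.0503). Ribosome biogenesis genes and MYC targets had 6 of 13 higher and 0 lower (7 and 0 adjusted over the list alone). Their median was 0.68 and their mean 0.72 (adjusted p = 0.00118, and adjusted p = 0.80 with an estimated correlation). Odc1 rose by 1.74 ± 0.18 (adjusted p = 1.77e-04) and Nop58, a ribosomal RNA processing factor, by 1.26. Interferon response genes had 7 of 9 lower and 0 higher (8 and 0 adjusted over the list alone). Their median was −1.77 and their mean −1.68 (adjusted p = 2.66e-05, and adjusted p = 0.80 with an estimated correlation). Usp18 was at −2.43, Mx1 at −1.92, Irf7 at −1.77 and Rtp4 at −1.74. T-lineage transcription factors had 1 of 10 lower and 0 higher (median −0.53, mean −0.67, adjusted p = 0.0283). The lower one was the proto-oncogene Myb (−2.39, adjusted p = 0.00111), whose other 2 probes, at −1.98 and −0.87, were not called. The T-lineage list's adjusted p was 0.80 with an estimated correlation, 0.288 without knockout replicate 1, 0.0748 without NHD13 replicate 1 and 0.10 with median scaling.

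Among the other T-lineage lists, DN3 genes had 3 of 16 higher and 1 lower (4 and 1 adjusted over the list alone), with a median of −0.16 and a mean of 0.21 (set test down, adjusted p = 0.814). Rag1 was 8.22, 11.5 and 12.1 and Ptcra 6.61, 9.93 and 10.2 in knockout replicates 1 to 3. Notch genes had 3 of 11 higher and 1 lower (median 0.22, mean 0.49, adjusted p = 0.556). Heyl, a Notch-responsive repressor, was at least 2.38-fold higher (adjusted p = 0.00572). Myc rose by 1.24 (adjusted p = 0.0248), which ended without NHD13 replicate 3 (adjusted p = 0.0881) or knockout replicate 2 (adjusted p = 0.0770) or 3 (adjusted p = 0.0642). Of 11 genes of CD4+CD8+ and later thymocytes 2 fell (5 adjusted over the list alone), with a median of −0.99 and a mean of −0.97 (adjusted p = 0.0816). Without knockout replicates 2 or 3 that list passed (adjusted p = 0.0067 and 0.0238), as it did with the background class as a block (adjusted p = 0.0231) or the sex covariate (adjusted p = 0.0433). Its array means against the wild-type mean were −2.14, 0.28 and 0.08 in knockout replicates 1 to 3, so most of the fall lies in replicate 1. Klf2 fell by 3.10 (adjusted p = 0.00217). T cell receptor signalling genes had 1 of 12 higher and 1 lower (1 and 2 adjusted over the list alone), with a median of −0.87 and a mean of −0.51 (adjusted p = 0.255, and 0.0398 without knockout replicate 2). Their array means against the wild-type mean were −3.02, 0.07 and 0.10 in knockout replicates 1 to 3. The NHD13 mean was −0.44, so only replicate 1 lay below it. Gamma delta markers had 2 of 7 lower (median −0.97, mean −1.12, adjusted p = 0.109), with the kinase gene Blk at −3.08 (adjusted p = 0.014). That list passed without knockout replicate 2 (adjusted p = 0.0398) or 3 (adjusted p = 0.0238) or NHD13 replicate 3 (adjusted p = 0.0430). Its array means against the wild-type mean were −1.34, 0.17 and 0.48 in knockout replicates 1 to 3. Without knockout replicate 1 Blk was at −1.87 (adjusted p = 0.00272).

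Of the remaining lists, NK and innate lymphoid markers had 1 of 10 higher and 1 lower (median 0.08, mean 0.10, set test down, adjusted p = 0.811), and Nkg7 fell by 2.34 (adjusted p = 0.00154). Dendritic cell markers had 2 of 10 lower (median −0.61, mean −0.48, adjusted p = 0.226, and 6.40e-04 with the background class as a block), with the plasmacytoid marker Siglech at −1.99 (adjusted p = 0.00286) and its other probe at −0.12. Myeloid markers had 0 of 15 called (median 0.37, mean −0.06, set test up, adjusted p = 0.971) and were down without knockout replicate 1 (adjusted p = 0.00330). B cell markers had 1 of 6 lower (median −0.33, mean −0.25, adjusted p = 0.510, and 0.0172 with the class as a block) and erythroid markers 1 of 3 (median −0.19, mean −1.87, adjusted p = 0.510). Here the class term is the gap between wild-type replicates 1 to 3 and 4 to 6, which also differ in sex. Dendritic and B cell markers were 0.98 and 0.83 log2 higher in replicates 1 to 3. The dendritic and B cell calls with the class block rest on that gap. Megakaryocyte and mast cell markers had 1 of 4 lower (median 0.32, mean −0.80, set test down, adjusted p = 0.782). Thymic stroma markers had 2 of 7 lower (3 adjusted over the list alone), with a median of −0.13 and a mean of −0.37 (adjusted p = 0.226), and p53 targets 2 of 13 (median −0.03, mean −0.13, adjusted p = 0.510). The BCL2 family had 1 of 9 higher (median 0.44, mean 0.31, adjusted p = 0.556). Immediate early and heat shock genes had 1 of 10 lower (median −0.07, mean 0.14, set test down, adjusted p = 0.732). Sex-linked genes had 0 of 4 called (median 0.54, mean 0.20, set test down, adjusted p = 0.971).

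The largest rise was in Igf2, a fetal growth factor (at least 143-fold, adjusted p = 2.60e-05), at 12.76 ± 1.54 against 5.26 ± 0.56, where 1 of 3 arrays detected it. It was followed by the metallothionein Mt1 (5.14), Rag1, Slc5a9 (at least 16.6-fold), Nrp1 (4.30 ± 0.30, adjusted p = 9.49e-06), Scara3 (at least 12.1-fold) and the collagen gene Col15a1 (at least 8.46-fold). Afdn (at least 9.02-fold), Cenpv (3.66), Stc1 (at least 8.54-fold), the receptor gene Neo1 (at least 6.90-fold) and the T cell inhibitory receptor Ctla4 (3.39) came next. The largest falls were in Olfm5 (at least 68.7-fold, adjusted p = 2.89e-05), Lyl1 (at least 54.0-fold), the actin-severing protein Scin (−6.10), Hba-a1 (−5.70), Ubqlnl (at least 29.4-fold) and Mrvi1 (at least 27.2-fold). The mast cell protease Cpa3 (−4.51), Angpt1, a ligand of vessel and stem cell niches (−4.37), the interleukin 10 receptor Il10ra (−4.21), Hbb-bt, Trgv5 (−4.13) and Clec4e (−4.11) followed. The other probe of Neo1 rose less (0.84). Hbb-bt and Trgv5 have close copies that their probes may also read. The call for Hbb-bt (−4.15, adjusted p = 0.0301) ended without any single array except knockout replicate 1, with an adjusted p of up to 0.104 (without NHD13 replicate 2).

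In this comparison limma called 4284 probes (2289 higher, 1995 lower in the knockout group), or 2329 genes (1361 higher, 968 lower). Without NHD13 replicates 2 or 3 it called 2357 and 2549, without knockout replicate 1 it called 4010, 3222 of them shared, and a fit of these 6 arrays alone called 1998. All NHD13 arrays lie in 1 background class and all knockout arrays in the other, so no value within a class can be had, and with the class as a term, estimated through the wild-type arrays, 3064 probes passed, only 1847 of them among the 4284.

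The comparison of the knockout group with wild type asks what the fusion still changes when Lyl1 is absent. HOX genes and cofactors had 9 of 19 higher and 0 lower (12 and 0 adjusted over the list alone). Their median was 2.03 and their mean 1.89 (adjusted p = 4.85e-09, and adjusted p = 0.0564 with an estimated correlation), and the adjusted p was 4.64e-10 without knockout replicate 1. Pbx3 was at least 13.6-fold higher (adjusted p = 9.24e-06), at 9.17 ± 0.27 in 3 arrays against 5.00 ± 0.26 in 6, of which 1 detected it. Hoxa5 was 11.5-fold higher (3.53 ± 0.25, adjusted p = 3.28e-05), Hoxa7 10.1-fold (3.34) and Hoxc6 at least 30.7-fold. The HOX list's mean was 1.65, 2.14 and 1.89 above wild type in knockout replicates 1 to 3. Lmo2 was at 0.56 ± 1.14 (adjusted p = 0.801), and at −1.55 (adjusted p = 0.11) without knockout replicate 1. Lyl1 was at least 3.47-fold lower (adjusted p = 9.24e-06), and Nup98 was at 0.12 (adjusted p = 0.728).

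Stem and progenitor genes had 4 of 16 higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 1.03 and a mean of 0.87 (set test up, adjusted p = 0.125). Without knockout replicate 1 the adjusted p was 0.983, with the test turned down. Without replicate 2 it was 0.00986 and without replicate 3 it was 0.0472. The list's mean was 2.18, 0.12 and 0.33 above wild type in knockout replicates 1 to 3. Early thymocyte regulators had 3 of 14 higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.77 and a mean of 0.66 (adjusted p = 0.415, and 0.0377 without knockout replicate 2). Their array means were 2.49, −0.34 and −0.15 in knockout replicates 1 to 3, so the rise of the mean lies in replicate 1. The members that rose included Hoxa9 (at least 6.58-fold) and Gfi1b (at least 4.5-fold, adjusted p = 0.0134). T-lineage transcription factors had 3 of 10 lower and 0 higher (6 and 0 adjusted over the list alone). Their median was −0.67 and their mean −0.90 (adjusted p = 9.49e-05, and adjusted p = 0.680 with an estimated correlation), and the adjusted p was 0.00320 without knockout replicate 1. Their array means were −1.91, −0.28 and −0.52 in knockout replicates 1 to 3. Those that fell were Bcl11b, which fixes T cell fate (−1.32, adjusted p = 0.0441), Myb (−1.08, adjusted p = 0.0391) and Gfi1 (−0.58, adjusted p = 0.0303). Their calls ended without knockout replicate 1 (adjusted p = 0.0983, 0.140 and 0.123), and those of Bcl11b and Gfi1 without replicate 3 (adjusted p = 0.0814 and 0.0819), that of Myb without replicate 2 (adjusted p = 0.0987). Leaving out single wild-type arrays also ended them, with an adjusted p of up to 0.0754 for Bcl11b (replicate 3), 0.0745 for Myb (replicate 5) and 0.0571 for Gfi1 (replicate 6). The other 2 probes of Myb, at −1.11 and −0.37, were not called.

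DN3 genes had 2 of 16 lower and 0 higher (4 lower and 1 higher adjusted over the list alone). Their median was −0.49 and their mean −0.65 (adjusted p = 0.010, and adjusted p = 0.680 with an estimated correlation), and the adjusted p was 0.452 without knockout replicate 1 and 0.152 against wild-type replicates 4 to 6 alone. T cell receptor signalling genes had 0 of 12 called, with a median of −0.93 and a mean of −0.95 (set test down, adjusted p = 0.00568). That list's adjusted p was 0.680 with an estimated correlation, 0.193 against wild-type replicates 4 to 6 alone and 0.983, in the other direction, without knockout replicate 1. Their array means were −3.02, 0.07 and 0.10 in knockout replicates 1 to 3, and those of the DN3 list −1.93, −0.01 and −0.01. Dendritic cell markers had 4 of 10 lower and 0 higher (5 lower and 1 higher adjusted over the list alone). Their median was −1.37 and their mean −1.09 (adjusted p = 0.0162, and adjusted p = 0.680 with an estimated correlation). It was 0.0630 without knockout replicate 2 and 0.211 against wild-type replicates 4 to 6 alone. Siglech fell by 2.66 ± 0.30 (adjusted p = 6.87e-04) and the antigen-presenting molecule H2-Ab1 fell by 2.44 (adjusted p = 0.0097). Of 9 interferon response genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.85 and a mean of 0.73 (adjusted p = 0.0469). They were Irf7 (1.48, adjusted p = 0.00943) and Isg15 (1.92, adjusted p = 0.0144, and 0.0552 without knockout replicate 3). That list's adjusted p was 0.680 with an estimated correlation, 0.477 without knockout replicate 3 and between 0.0652 and 0.0765 without wild-type replicate 1, 2, 4 or 6. It also lay between 0.0583 (the mean of a gene's probes) and 0.163 (the replicate number as a block) with median scaling, the class as a block or either wild-type set. Cell cycle genes had 0 of 20 called (median −0.21, mean −0.19, adjusted p = 0.0698, 0.00986 without knockout replicate 2, 0.0445 without wild-type replicate 3 and 0.0428 with the sex covariate). Ribosome biogenesis genes and MYC targets had 2 of 13 lower (median −0.08, mean −0.12, adjusted p = 0.382).

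Of the other lists, Notch genes had 2 of 11 higher (4 higher and 2 lower adjusted over the list alone), with a median of 0.27 and a mean of 0.34 (adjusted p = 0.445). Heyl was at least 2.42-fold higher (adjusted p = 0.00337). Genes of CD4+CD8+ and later thymocytes had 1 of 11 higher (median −0.40, mean −0.59, set test down, adjusted p = 0.164, 0.0241 without knockout replicate 2 and 0.0281 with the mean of a gene's probes). Their array means were −2.14, 0.28 and 0.08 in knockout replicates 1 to 3, so the fall of the mean lies in replicate 1. Myeloid markers had 0 of 15 called (median 0.21, mean 0.16, set test down, adjusted p = 0.998, and 3.15e-06 without knockout replicate 1). Gamma delta markers had 1 of 7 lower (median 0.19, mean −0.23, set test down, adjusted p = 0.415). NK and innate lymphoid markers had 0 of 10 called (median −0.73, mean −0.51, adjusted p = 0.0698, 4.48e-05 without knockout replicate 3 and 0.0193 with median scaling). B cell markers had 0 of 6 called (2 lower adjusted over the list alone), with a median of −0.52 and a mean of −0.38 (adjusted p = 0.136). That list was called down with the class as a block (adjusted p = 0.00959), the replicate number as a block (adjusted p = 0.0115), wild-type replicates 1 to 3 alone (adjusted p = 0.00886) and median scaling (adjusted p = 0.0240). All of these but median scaling are in effect the same comparison, that with wild-type replicates 1 to 3. Erythroid markers had 1 of 3 higher (2 adjusted over the list alone), with a median of 0.69 and a mean of 0.81 (adjusted p = 0.256). Megakaryocyte and mast cell markers had 0 of 4 called (median 0.53, mean 0.04, adjusted p = 0.746). Thymic stroma markers had 1 of 7 higher (2 higher and 2 lower adjusted over the list alone), with a median of 0.09 and a mean of 0.03 (set test down, adjusted p = 0.746). Of 13 p53 targets 2 rose and 1 fell (2 and 2 adjusted over the list alone), with a median of 0.27 and a mean of 0.02 (adjusted p = 0.746). The death receptor gene Tnfrsf10b was at −1.84 (adjusted p = 0.00697). The BCL2 family had 1 of 9 higher (3 higher and 1 lower adjusted over the list alone), with a median of 0.42 and a mean of 0.41 (adjusted p = 0.125, and 0.0285 without knockout replicate 1). Immediate early and heat shock genes had 0 of 10 called (median −0.05, mean −0.03, adjusted p = 0.607), and sex-linked genes 0 of 4 (median −0.43, mean −0.19, adjusted p = 0.607).

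Igf2 rose most (91.1-fold, 6.51 ± 0.50, adjusted p = 4.94e-05). By fitted log2 change it was followed by Hoxc6, Pbx3, Neo1 (at least 7.03-fold), Hoxa5, Igf2bp3, which binds fetal messenger RNAs (3.43, adjusted p = 0.012), Hoxa7 and Hoxa9. The places of genes with only a lower bound, such as Neo1, are not firm. The integrin gene Itga9 (3.30 ± 0.34, adjusted p = 4.10e-04), Isoc2a (3.29), the developmental regulator Eya1 (at least 5.95-fold, adjusted p = 3.28e-05) and Hoxb7 (at least 5.46-fold) came next. The largest falls were in the IgM receptor gene Fcmr, the sodium channel subunit Scn4b (−3.31, adjusted p = 0.00313), Scin (−2.98), Gprc5b (at least 5.37-fold, adjusted p = 1.53e-04), Siglech and H2-Eb1. Dgkeos (−2.59, adjusted p = 0.0291), Fcrla, Gprasp2 (at least 4.24-fold, adjusted p = 4.14e-04), Lyl1, Klra1 and H2-Ab1 followed. The other probes of Neo1 (0.78), Itga9 (0.61), Scn4b (−0.22) and Gprc5b (−0.23) changed less, and those of Igf2bp3 ran from 0.06 to 3.79. Leaving out knockout replicate 1 ended the call for Fcmr (−3.93, adjusted p = 0.0233, then 0.0932) and Fcrla (−2.58, adjusted p = 0.0329, then 0.120). It also ended those for H2-Eb1 (−2.66, adjusted p = 0.0183, then 0.0596) and Klra1 (−2.46, adjusted p = 0.0175, then 0.0638), whose probe may also read other family members. Without knockout replicate 2 the adjusted p was 0.0701, 0.0799, 0.0508 and 0.0516 for these 4 genes. For Fcrla it was also 0.0590, 0.0569 and 0.0566 without wild-type replicates 1, 2 and 3. For Dgkeos it was 0.0508 without wild-type replicate 1 and 0.0531 without replicate 5. Without knockout replicate 1 Dgkeos fell less, by 1.35, and stayed called (adjusted p = 0.00986).

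For the knockout group against wild type limma called 1953 probes (831 higher, 1122 lower), or 871 genes (471 higher, 400 lower). It called 1123 probes without knockout replicate 1, 867 of them shared, and 1273 without replicate 3. Median scaling called 2996 probes, 2218 of them higher, with the median of all genes at 0.333 in place of 0.084, and against wild-type replicates 1 to 3, of the same background class, 1751 probes passed.

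Last, the changes of both transgenic groups against wild type were set side by side, to see how far NHD13 changes remained without Lyl1. Of the 2541 genes called between NHD13 and wild type, 1395 were called in the opposite direction in the knockout group against NHD13. Both comparisons use the NHD13 arrays, so noise or background in these alone can add to that count. In 20 simulations with a knockout group equal to NHD13 the count was 0. Equal groups give almost no calls between them, so that 0 cannot measure what the shared arrays add to the 1395. With the 6 transgenic arrays assigned to the groups in the 19 other ways it was at most 402, against 1551 for the real assignment in the same fit, which adjusts over genes. Neither removes the background class, which all NHD13 arrays share. Another 274 were called in the same direction in the knockout group against wild type, where some genes are in both counts, and 901 were in neither. Of the 274 shared genes 148 were higher, Pbx3, Hoxa5 and Hoxa7 among them, and 126 lower. Independent lists of these sizes share 105 genes, and 51 genes were called in opposite directions. Simulated groups without change shared 0, but such groups give almost no calls, so that 0 is no reference for the 274. With the wild-type arrays divided between both comparisons, so that no array served in both, the shared count averaged 99.6 (66 to 220 over 20 divisions) against 39.7 for independent lists. Without NHD13 replicate 2 the shared count was 171 and without replicate 3 it was 180. Median scaling gave 506. The covariance of the 2 sets of changes over 10497 genes was 0.136 ± 0.0204 (SD over the 20 divisions, r = 0.273 across genes, which are not independent replicates). It was 0.159 with all wild-type arrays in both, 0.0313 in simulated groups without change and 0.0815 without knockout replicate 1. On a scale where 0 is the wild-type mean and 1 the NHD13 mean over the 2541 genes, knockout replicates 1 to 3 lay at 0.404, 0.122 and 0.220.

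**Figure D3:**
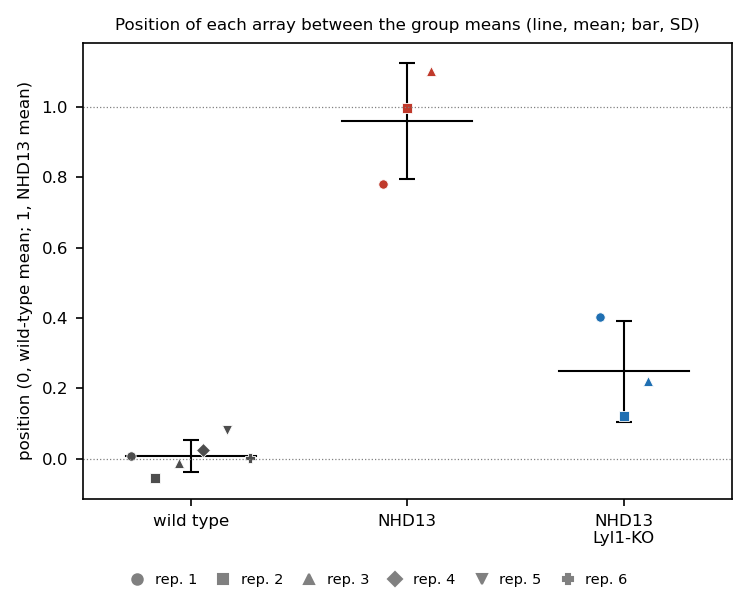
Position of each of the 12 arrays between the wild-type mean (0) and the NHD13 mean (1) over the 2541 genes called between these groups (vertical axis, no unit); each array was left out of its own group's mean, points are arrays with a marker for their replicate number, the line is the group mean and the bar its SD. Wild-type arrays lie between −0.055 and 0.082, NHD13 arrays between 0.780 and 1.10, and the knockout arrays between 0.122 and 0.404. The genes were picked on the wild-type and NHD13 arrays shown, which can pull the knockout arrays toward 0.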

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

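The splits of the samples and the test of the run or handling behind the background classes were planned; all other tests of this part were chosen after the results were seen.

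Among the 6 wild-type arrays, 149 values (levels of the genes named in the text, list means, array totals and positions) were searched for an array far from the 5 others, and 6 had one, where chance gives about 1 in 20. Gprc5b was high in wild-type replicate 3 (8.53, nearest 7.82), Hoxa2 in replicate 6 (6.18, nearest 5.11), Hoxc6 in replicate 1 (5.16, nearest 4.83), Stfa1 in replicate 5 (5.04, nearest 4.76) and Zfpm2 in replicate 2 (5.24, nearest 4.72), and Trim6 was low in replicate 1 (4.53, nearest 4.78). Replicate 1 appears for 2 genes, in opposite directions, and 6 of 149 is no more than chance gives. Groups of 3 were not searched.

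Knockout replicate 1 stood apart from replicates 2 and 3, with genes of myeloid granules high (Mpo 14.3 against 5.27 and 4.64, Prtn3 13.4 against 4.60 and 4.56, Elane 11.5 against 4.90 and 4.86) and T cell genes low (Zap70 6.71 against 12.02 and 12.17, Cd2 4.65 against 10.6 and 10.6). An NHD13 array under the wrong label would show Lyl1, but its detection p was 0.406, and a failed array would detect few probes, but it detected 17600. Thymocytes like those of replicates 2 and 3, diluted by cells without T cell genes, would lower these genes by 1 amount, down to the background. Over 19 such genes 18 were lower, with differences from −6.06 to 0.68 (median −3.53). Their SD of 1.82 was 3.92 times that between replicates 2 and 3 (0.464). Cd2, Lef1, Themis and Dntt lay under the signal at which detection starts on that array (5.44). Other cells that express some of the 19 genes would widen the SD too, so the SD cannot decide on dilution. Zap70 (−5.39) and Cd3g (−1.41), both above that signal, fell by unlike amounts, which dilution by cells that lack both would not give. A thymus with cells of another kind or stage among the sorted ones stays open, though the gate on CD4 and CD8 would not remove myeloid cells. The design holds no group that would test a biological explanation, and none was tested.

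Wild-type replicates 1 to 3 differed from replicates 4 to 6 in 1567 probes (702 higher, 865 lower), or 675 genes, 30 of them on X or Y, with B cell markers 0.83 higher (2 of 6 called), dendritic cell markers 0.98 higher (3 of 10) and myeloid markers at −0.67 (0 of 15). Sex as the cause of the background classes was excluded, since the class of the male wild-type arrays holds 2 female ones. For the run or handling that the classes mark, the difference between the wild-type sets correlated across genes at r = 0.0949 with that between the classes among the other arrays, and at 0.0515 to 0.122 on leaving out 1 array; the bound of 0.1 was set in advance, and the first verdict was that the value lay under it, but its spread crosses the bound, so it was left open. Sex as the cause of the expression difference gave r between 0.338 and 0.340 across the called genes, depending on the female array, which leaves it open. Sex and run cannot be told apart here, because wild-type arrays of 1 sex all lie in 1 class.

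Interferon response genes were higher in NHD13 than in wild type and lower again without Lyl1, though both list calls were lost with an estimated correlation (adjusted p = 0.234 and 0.80). Wild-type replicates 4 to 6 share the background class and the sex of the NHD13 arrays. Class or sex could account for the rise only if these replicates were as high. The lowest NHD13 list mean lay 1.68 log2 above the highest of them. The mean difference was 2.39 and 9 of 9 members were higher, which argues against both as the cause of the rise. The fall without Lyl1 sets 1 class against the other, so an effect of the class on it cannot be told apart. An effect of the fusion that depends on Lyl1 is a candidate explanation, found in these data and not tested. Infection, housing and the day of preparation were not recorded in the labels, were not tested and stay open.

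The samples of each comparison were also regrouped in every other way, and all 12 arrays in 100 regroupings for the genes shared by both transgenic groups, to see whether chance gives as many calls. For NHD13 against wild type 1 of 84 splits, the real one, called 4295 probes, and the highest other called 2182; that split sets wild-type replicates 1 to 3 apart, so it follows background class and sex, and within the class of the NHD13 arrays 2780 probes passed. For the knockout group against wild type 1 of 84 splits, the real one, called 1953 probes, and the highest other, again wild-type replicates 1 to 3, called 1361; within the class 1751 passed. In both comparisons the share of splits excludes chance for the counts of probes only if the arrays are exchangeable. The class and sex that set wild-type replicates 1 to 3 apart put that in doubt, and no splits within a class were run. For the knockout group against NHD13 the 10 splits are too few for a share under 0.05; the real split (1 of 10 as large) called 4284 probes and the highest other 69. For the 274 genes called against wild type in both transgenic groups, 1 of 100 regroupings was as large, the real one (highest other 3). Regroupings that mix the groups can lose most calls of each comparison, which leaves few genes to share. They therefore cannot decide on overlap by chance, for which independent lists give 105 genes. Chance cannot be excluded for the number of lists called. As many as the 7 of NHD13 against wild type came from 10 of 84 splits (highest other 9). For the knockout group against wild type 56 of 84 splits gave as many as the 6 (highest other 13). The 10 splits of the knockout group against NHD13 are too few, with 4 lists in the real one and 12 in the highest other (10 of 10 as large).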

How the results depend on the processing

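The background class as a block, sex as a covariate and the restriction to 1 set of wild-type arrays were chosen after the data were seen; all other alternatives were planned. The planned fit with the chip as a block was not run, since the labels give no chip. The replicate numbers do not pair the samples: arrays with the same number deviated from their group means with correlations between −0.149 and 0.167. The replicate number as a block gave 3517, 3185 and 1393 probes and 5, 4 and 6 lists in the 3 comparisons, in the order of the report; it compares the knockout group with wild-type replicates 1 to 3 in effect, and put Lmo2 at −0.19 there.

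For NHD13 against wild type (4295 probes) a minimum change of 2-fold left 2164 probes, by construction. Wild-type replicates 4 to 6 alone gave 2780 and replicates 1 to 3 alone 4475, so the count depends on the wild-type set and not only on the number of arrays; without 1 array the count ran from 2246 to 4322. For the knockout group against NHD13 (4284) a fit of these arrays alone gave 1998 and a minimum change of 2-fold 2574; without 1 array it ran from 2357 to 4648. For the knockout group against wild type (1953) median scaling gave 2996, the class as a block 3045 and a minimum change of 2-fold 1152; without 1 array it ran from 1123 to 1613. With median scaling the median of all genes was 0.333 in place of 0.084, and 74.0% of its calls were higher. The class block has the log2 changes of the comparison with wild-type replicates 1 to 3 alone, where 1751 probes passed. The gap between 3045 and 1751 thus lies in the estimated spread. The cause of these shifts was not tested further. The authors' deposited table, an offset of 50, no filter, a detection p-value under 0.01, eBayes with trend and robust and the sex covariate kept each of the 3 counts within 1.5 times.

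The lists called (7, 4 and 6) dropped to 0, 0 and 0 with an estimated correlation and were 10, 7 and 1 with fry, which asks another question. For the knockout group against wild type fry ended the calls of DN3 and T cell receptor signalling genes (adjusted p = 0.338 for each), T-lineage factors (adjusted p = 0.0598), dendritic cell markers (adjusted p = 0.0606) and interferon genes (adjusted p = 0.177), and for the knockout group against NHD13 that of T-lineage factors (adjusted p = 0.0949). The class as a block called 7 lists for the knockout group against NHD13, and wild-type replicates 4 to 6 alone called 2 for the knockout group against wild type. Without 1 array the lists called ran from 6 to 8, 3 to 7 and 5 to 9. The covariance of both transgenic groups' changes (0.136) was 0.159 with undivided controls and 0.0781 with no filter on dim probes, where many probes hold background alone; without 1 array it ran from 0.0815 to 0.177. The genes called in both (274) were 99.6 with divided controls and 506 with median scaling, and ran from 171 to 282 without 1 array.

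Among single named genes, Cd8b1 turned to −3.23 with the mean of its probes. Lmo2 in the knockout group against wild type turned to −0.55 with array weights and −0.19 against wild-type replicates 1 to 3. The class as a block gave −0.19 too, as it is the same comparison in effect. On leaving out 1 array the change of Lmo2 lay between −1.55 (without knockout replicate 1) and 1.65 (without replicate 2). Apart from left-out arrays, 911 of 1021 values of 73 named genes for NHD13 against wild type kept direction and side of the threshold, 673 of 767 (64 genes) for the knockout group against NHD13 and 564 of 670 (48 genes) for the knockout group against wild type; with 1 array left out it was 568 of 657, 306 of 384 and 329 of 432. Signal over background limits what can be seen: probes under the detection limit on more than 9 arrays were not tested, and a fold against an undetected group is only a lower bound.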

Other observations

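The tests on Ubqlnl and its neighbours and on the neighbours of Lyl1 were chosen after the results were seen, and so were the genes named here; the prediction on imprinted genes was written before the values of the genes it covers were seen.

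A run of 7 neighbouring measured genes rose in NHD13 and fell again without Lyl1. Ubqlnl and Olfm5, both among the largest changes of the report, lie side by side, and around them Olfr643 (at least 2.56-fold, adjusted p = 0.00132), Olfr644 (at least 2.69-fold, adjusted p = 1.19e-04), Ubqln5 (at least 3.72-fold, adjusted p = 1.10e-05), Trim6 (at least 1.19-fold, adjusted p = 0.00252) and Trim34a (log2 change 1.55, adjusted p = 0.00318) rose in NHD13 by limma's test. All fell in the knockout group against NHD13, the first 4 by at least 2.55-fold, 2.69-fold, 3.72-fold and 1.19-fold with Trim34a at −2.36 on the log2 scale, and both calls held without any single array. No wild-type or knockout array detected the first 4. Trim34a was on in all groups, at 8.06 to 8.65 in wild type and 6.97 to 7.98 in the knockout group, and Trim6 reached only 5.55 to 5.77 in NHD13. Ubqlnl had a log2 signal of 9.86, 10.1 and 10.9 in NHD13 replicates 1 to 3 and between 4.62 and 5.30 on all knockout arrays. The beta-globin genes Hbb-bs (4.18 in NHD13, adjusted p = 0.00961, and 0.0535 without NHD13 replicate 2) and Hbb-bt (4.51, adjusted p = 0.0106, and 0.0555 without NHD13 replicate 2) lie 1 measured gene away, across the globin gene Hbb-bh1, which was not called (adjusted p = 0.519), but unlike the run they stayed high in knockout replicate 1 (12.3 and 12.2).

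Chance placement was tested by shuffling the 593 genes that rose in NHD13 and fell without Lyl1 over the gene order. This test replaced a first one, the share of windows with as many, after that result was seen, because windows share genes. Hbb-bt was then also dropped from the pattern. Windows of 5 neighbours centred on 10399 genes held 5 such genes in 3 cases, all of them in this run, and 5 of 1000 shuffles put as many into any window, a share of 0.006 with the real order counted, which argues against chance. Shuffling takes genes as independent, and probes of similar neighbours that read each other were not tested. A test of a transgene inserted beside these genes was run and dropped, because the genes had been picked as lower in the knockout group than in NHD13. Against wild type, the 7 genes lay between −0.81 (Trim34a) and 0.17 (Olfr643) log2 in the knockout group and were not called. The labels name the transgene in both groups, but whether both carry the same insertion was not checked. The 7 genes were also picked as lower in the knockout group than in NHD13, so a return toward wild type was partly built in. These values therefore cannot decide on an insertion. An insertion beside these genes stays open, whether or not its effect depends on Lyl1. Control of this region by Lyl1 or by what depends on it, a strain-specific segment around these genes in the NHD13 mice, and cells of another kind that express them were not tested.

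Igf2 was higher in the knockout group than in both others, and so were Cdkn1c, a brake on the cell cycle (2.84 against NHD13, adjusted p = 0.00208; 3.17 against wild type, adjusted p = 0.00132), the growth factor Pdgfa (3.08, adjusted p = 0.00153; 3.05, adjusted p = 0.00166), Neo1, Scara3 and Itga9. In total 393 genes were called against both groups in 1 direction, 215 higher and 178 lower in the knockout group. On knockout replicates 1 to 3 the log2 signal of Cdkn1c was 8.19, 9.34 and 8.67 and that of Pdgfa 9.24, 9.10 and 7.63. The log2 change of Scara3 against NHD13 was 4.18, and 5.61 without knockout replicate 1, where its signal was thus lower than in the others. Igf2, Cdkn1c and Snurf are imprinted genes, which are read from the copy of 1 parent, although Snurf was on in knockout replicates 1 and 3 (7.98 and 8.99) and not in replicate 2 (4.64), and its call ended without replicate 1 (adjusted p = 0.101 against NHD13). The hypothesis that imprinted genes rose as a class was tested on a list of 35, without these 3 and without Dlk1 (at least 5.28-fold higher than in NHD13, adjusted p = 0.0279, and 2.22 on the log2 scale against wild type, adjusted p = 0.0582), whose values had been seen. The call for Dlk1 ended without NHD13 replicate 2 (adjusted p = 0.0865) or 3 (adjusted p = 0.0807). Of the 8 others measured 0 were called higher against both groups, against 2.02% of the remaining genes (1-sided Fisher exact p = 1), with medians of 0.30 and 0.20. Grb10, 1 of the 8, was at least 5.57-fold higher than in wild type (adjusted p = 0.00687) but missed the threshold against NHD13 (log2 change 1.77, adjusted p = 0.0535), which it passed without knockout replicate 2 (adjusted p = 0.0341) or 3 (adjusted p = 0.0495). Against NHD13, Gnas was lower (−0.96, adjusted p = 0.0154) and Ube3a higher (0.71, adjusted p = 0.0286), and neither was called against wild type (−0.32 and 0.27). The call for Ube3a ended without any single NHD13 or knockout array, with an adjusted p of up to 0.0786 (without knockout replicate 1). With so few genes a class effect stays open.

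Genes next to Lyl1 were looked at because the deleted copy of a gene often carries flanking sequence of another strain. Of its 20 nearest measured neighbours 2 were called against both groups in 1 direction, Gadd45gip1 higher (at least 3.03-fold and 2.82-fold) and Calr lower (−1.84 and −1.42), against 3.74% of all genes. Windows of 20 neighbours held as many in 1805 of 10074 places (17.9%), so chance placement was not excluded, and 4 of 50 and 7 of 100 neighbours were called in wider windows. Dimming of probes by foreign sequence would only lower signals, and 1 of the called neighbours was higher, so such dimming cannot be the whole cause. This pattern had been meant for weighing with the others and was replaced by the interferon genes once its test had come out.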
